A study of Mus musculus with 16 samples.

How the data were processed

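RNA sequencing was analysed in 16 libraries of primary cortical neurons, cultured from Swiss Webster mouse embryos taken on embryonic day 16. On day 5 in vitro the neurons received a lentivirus carrying exon 1 of huntingtin (Htt) together with a second lentivirus carrying a short hairpin RNA (shRNA), and RNA was collected on day 10. Exon 1 encoded a wild-type tract of 25 glutamines (25Q) or a mutant tract of 72 glutamines (72Q), the kind of expansion that causes Huntington disease. The 4 groups were 25Q with a control shRNA against luciferase, 72Q with the same control, 72Q with Twist1 shRNA 1 and 72Q with Twist1 shRNA 2, each with n = 4 libraries. Twist1 is a basic helix-loop-helix (bHLH) transcription factor of mesoderm and neural crest. Ribosomal RNA was removed with Ribo-Zero, per the labels. Groups were taken from the sample titles, and the description labels assigned each library to 1 of the experiments exp107, exp108, exp109a and exp109b, with 1 library of each group in each experiment.

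Reads were aligned with STAR 2.0.4b and assigned to genes with featureCounts 1.45 of the Subread package on the build GRCm38, per the submitters' processing notes. Strandedness, the treatment of multi-mapping reads and the annotation release are not given in the sources used here. Without strand, reads of a gene and an antisense or overlapping partner cannot be told apart, and genes with close paralogs are uncertain in the same way. The authors deposited raw read counts per Ensembl gene for 41388 genes in each library, and these counts were the input of every test. Deposited CPM values (counts scaled to library size) equalled each count over the library's total, the largest difference being 2.5e-11, and deposited RPKM values equalled that CPM per kilobase of the listed gene length, with a largest difference of 3.8e-11. Neither deposited CPM nor deposited RPKM entered a test. Totals ranged from 15814525 to 19533034 counts per library. Between 20188 and 20426 genes had at least 1 count in the 25Q libraries, fewer than the 20488 to 21433 of the 72Q libraries. Mitochondrial-genome transcripts made up 2.41 to 2.78% of counts in the 25Q libraries and 3.16 to 3.59% in the 72Q control libraries. The share was 2.39 to 3.26% with Twist1 shRNA 1 and 2.10 to 2.78% with Twist1 shRNA 2. Gene symbols came from GENCODE release M21, also on GRCm38, in which 40340 of the listed identifiers (97.47%) had a symbol, and coordinates are those of the deposited files unless said otherwise.

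Low genes were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 15103 genes. Libraries were scaled by TMM factors, and the quasi-likelihood test of edgeR (glmQLFit with robust estimation, glmQLFTest) was fitted to all 16 libraries with group and experiment as terms. The common biological coefficient of variation was 5.24%. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05, and every adjusted p given for a gene is of this kind. A named gene is said to have risen or fallen only where its adjusted p was under the threshold. Log2 fold changes used a prior count of 2 and are given ± SE, and CPM values in the text are TMM-scaled means ± SD with n = 4. Summed levels of receptor genes are the exception, being scaled to library totals alone. The comparisons were 72Q against 25Q with control shRNA, each Twist1 shRNA against the control in 72Q, their mean against the control in 72Q, shRNA 1 against shRNA 2, and their mean in 72Q against 25Q. The experiment label was used as a block because libraries of 1 experiment deviated together from their group means, with correlations across genes of 0.319 to 0.703 for every pair of groups, against means of -0.191 to -0.142 between experiments. Genes are not independent replicates of such a correlation. The replicate number in the titles matched the experiment in all 72Q libraries but in 1 of 4 libraries of 25Q, and libraries of 25Q and 72Q with the same number had correlations from -0.308 to 0.374. Pairs of replicates differed by 2.86 to 22.72 times sampling noise (chi-square per degree of freedom), so no library appeared to be deposited more than once. Nothing beyond the experiment labels says whether replicates were separate cultures, so p-values measure the spread between these samples.

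The main design, the alternatives listed at the start, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took Twist1 and Htt, the 12 highest and 12 lowest called genes of 72Q against 25Q, 10 and 10 of the genes called with both Twist1 shRNAs in 1 direction, 5 and 5 called with each shRNA alone (unadjusted p over 0.05 for the other), 10 and 10 changed in 72Q and moved the opposite way with both shRNAs, and 6 and 6 of shRNA 1 against shRNA 2. Genes called with both shRNAs were ranked by the mean of their log2 fold changes, which can rest mainly on 1 shRNA. Candidates needed a mean of at least 1 CPM over the 16 libraries, the same sign in all 4 experiments and a symbol that is not a predicted model, pseudogene or small RNA. From each gene list, members with the smallest p in a comparison were added, at most 4 per list and comparison. Results of some genes taken by the rule are not reported here. The 22 lists covered activity-regulated genes, striatal-type neuron genes lowered in Huntington disease, the glutamatergic synapse, inhibitory neurons and GABA receptors, voltage-gated channels, cortical projection neuron identity, cholesterol biosynthesis, heat shock and cytosolic chaperones, the unfolded protein and integrated stress response, p53 targets and apoptosis, oxidative phosphorylation, HOX and other developmental transcription factors, DNA methylation and chromatin machinery, bHLH and Id factors, epithelial-mesenchymal transition genes of the Twist1 literature, and the interferon response. Markers of astrocytes, microglia and macrophages, the oligodendrocyte lineage, endothelial, mural and meningeal cells, neural progenitors and proliferation, and neurons in general completed them. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists and the 3 main comparisons, and again with an estimated correlation. For shRNA 1 against shRNA 2 the lists were adjusted on their own.

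Because the 72Q control libraries enter the 72Q effect and both shRNA effects, 20 simulated data sets without shRNA effects and 6 divisions of the 72Q controls into pairs were used. The simulated sets show what shared controls give where no gene changes with an shRNA. They do not measure what shared controls add to counts of genes that do change. Overlaps expected of independent lists were computed as n1 × n2 / N over the genes tested. Annotated 3' UTRs of 13598 genes were searched for 15882 words of 7 bases that might separate genes by their fold change, as a seed match of a small RNA would. Steps were tested on simulated data of 15103 genes of which 200 were changed, 50 at each of 4 sizes. For 72Q against 25Q, 20, 35, 41 and 47 of 50 genes were recovered at 1.2-, 1.5-, 2- and 4-fold, and 6 of 149 called genes were unchanged ones. For Twist1 shRNA 1 these numbers were 23, 32, 45 and 50, with 12 of 162 calls false. For shRNA 2 they were 24, 36, 44 and 50, with 7 of 161 false. A list shifted in the simulation was found and 0 of the other lists were called. Genes of this simulation were drawn independently, so it does not test the preset correlation where members of a list move together. A planted 3' UTR word was recovered in 20 of 20 simulations. Alternatives replaced or dropped the block, joined exp109a and exp109b, used the compared libraries alone, RLE factors, DESeq2 1.42.0, limma-voom with sample weights, other filters on low counts, libraries without ribosomal, mitochondrial and small RNA genes, and each library left out in turn. Upper-quartile factors and no scaling beyond library totals were added after the data had been seen. For genes at 0 counts in all libraries of a group, the fold is a lower bound against a floor of 3 counts over the group, and ratios of summed counts carry 95% exact binomial intervals. Such intervals and floors cover counting error only. Level of the transduced exon 1 was not analysed here.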

Results

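Transcript levels were measured in 4 groups of mouse cortical neurons with n = 4 libraries each, as read counts per gene, at 15814525 to 19533034 total counts per library. Of 15103 genes tested, 8628 differed between 72Q and 25Q, 6999 between Twist1 shRNA 1 and the control shRNA in 72Q, and 6307 between Twist1 shRNA 2 and the same control. In a principal component analysis, PC1 held 41.9% of the variance and separated the 25Q libraries, at 47.9 to 50.9, from all 72Q libraries, which lay between -37.0 and 5.15. PC2, with 15.3% of the variance, set the shRNA 1 libraries, at 28.1 to 37.4, apart from the other 12.

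The series asks what part Twist1 plays in the transcriptional changes caused by mutant huntingtin, so Twist1 itself was examined in every group. Twist1 (ENSMUSG00000035799, chr12:33957671-33959817) was near the floor in 25Q neurons at 0.271 ± 0.225 CPM and stood at 4.15 ± 0.763 CPM in 72Q neurons with the control shRNA. The log2 fold change was 3.47 ± 0.27 (adjusted p = 4.77e-12, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), from 18 summed counts in 25Q and 294 in 72Q, a ratio of 15.2 (95% interval 9.45 to 26). Twist1 shRNA 1 lowered it to 1.57 ± 0.452 CPM, a log2 fold change of -1.35 ± 0.20 (adjusted p = 1.52e-06). With Twist1 shRNA 2 it fell to 1.64 ± 0.403 CPM, a log2 fold change of -1.29 ± 0.19 (adjusted p = 2.97e-06). Between the shRNAs the difference was -0.066 ± 0.23 (95% interval -0.507 to 0.375, adjusted p = 0.826). With the shRNAs, Twist1 stayed above its 25Q level, their mean lying 2.14 ± 0.28 log2 units higher (adjusted p = 1.04e-07). The mouse Htt gene (ENSMUSG00000029104, chr5:34761740-34912534) was at 276 ± 35.4 CPM in 25Q and 243 ± 14.4 CPM in 72Q, a log2 fold change of -0.18 ± 0.053 (adjusted p = 0.00528) with the same sign in 3 of 4 experiments, and the call was lost without the experiment block, with upper-quartile factors (-0.113) and without scaling (-0.042). Htt was 0.053 ± 0.053 log2 units from its control with shRNA 1 (adjusted p = 0.434) and -0.13 ± 0.053 with shRNA 2 (adjusted p = 0.0475), a call that most alternatives ended. It was not called where any of the 4 shRNA 2 libraries or the 72Q control library of exp107 or exp108 was left out, at values between -0.145 and -0.093. Whether reads of the transduced exon 1 count toward this gene is not given in the sources used here, so neither level nor fold can be assigned to the mouse transcript alone.

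**Figure D1:**
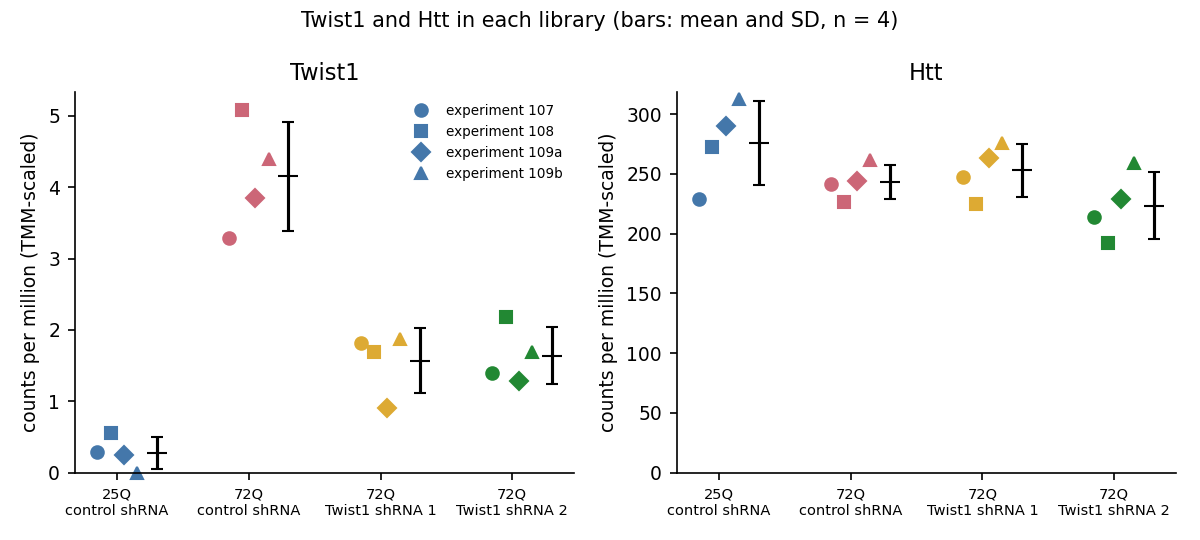
Twist1 and Htt levels in CPM (TMM-scaled) for each of the 16 libraries by group, with marker shapes for the 4 experiments and bars for the mean and SD (n = 4). The 72Q control group averages 4.15 CPM of Twist1 against 0.271 in 25Q and 1.57 and 1.64 with the shRNAs.

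Neurons with 72Q Htt contained transcripts of developmental transcription factors that were nearly absent with 25Q, while transcripts such as those of Gpr6 and Rgs4 fell. Pou4f1, a POU factor of sensory neurons, rose from 0.271 ± 0.131 to 14.2 ± 1.63 CPM (log2 fold change 5.20 ± 0.17), and Tal1, a bHLH factor of blood and inhibitory neuron development, from 2.27 ± 0.265 to 36.9 ± 7.42 CPM (3.95 ± 0.13). The constitutively active receptor gene Gpr6 fell from 45.4 ± 7.5 to 2.25 ± 1.07 CPM (-4.29 ± 0.26), and Rgs4, a brake on G protein signalling, from 280 ± 13.4 to 46.2 ± 15.6 CPM (-2.65 ± 0.21). Adjusted p values of these genes ranged from 2.71e-20 to 1.95e-06. In all, 4431 genes rose and 4197 fell, 555 and 634 of them by at least 2-fold. Called genes were higher in 51.4% of cases, and in 60.7% with upper-quartile factors and 69.7% without scaling beyond library totals, which moved the median of all genes from 0.03 to 0.092 and 0.163 log2 units.

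Others among the 12 genes with the largest rise were Lhx4 and Lhx8, LIM-homeodomain factors of motor and cholinergic neurons, at 4.66 ± 0.25 and 4.03 ± 0.31 log2 units. Also in this group were Hoxc13 (4.31 ± 0.31), a HOX factor of hair and nail, Foxd1 (4.14 ± 0.30), a factor of kidney stroma, Shox2 (3.74 ± 0.34), a limb and heart homeobox factor, and Ebf3 (3.82 ± 0.27), an early B-cell factor family member. The T-box factors Tbx20 and Tbx3 rose by 3.97 ± 0.36 and 3.84 ± 0.33, the POU factor Pou4f2 by 3.73 ± 0.34 and the insulin receptor substrate Irs4 by 4.08 ± 0.25. The rule had required a call and the same sign in all 4 experiments, and adjusted p values of the 12 were 5.77e-10 or less. Since several had few or no counts in 25Q, their fitted folds depend on the prior count. Tbx20 and Pou4f2 had 0 counts in the 25Q libraries and were at least 36.9-fold and at least 30.7-fold higher in 72Q. Ratios of summed counts were 113 (20 to 4520) for Tbx3 from 1 count, 79.5 (21.7 to 662) for Foxd1 from 2 counts, and 67.6 (22.8 to 330) for Hoxc13, 54.6 (18.4 to 267) for Lhx8 and 43.7 (14.7 to 215) for Shox2 from 3 counts each.

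Among the 12 largest decreases were receptors and membrane proteins. The melanocortin receptor gene Mc4r fell by 2.44 ± 0.15 and the serotonin receptor gene Htr1a fell by 2.43 ± 0.12 on the log2 scale, Htr1a from 20.4 ± 1.66 to 3.68 ± 1.25 CPM. Cav1, the caveolar scaffold, dropped by 2.55 ± 0.17, the sialyltransferase gene St3gal1 fell by 2.71 ± 0.24, the ubiquitin ligase gene Pdzrn3 fell by 2.41 ± 0.11 and Nwd2 fell by 2.70 ± 0.17. Fst, the activin antagonist follistatin, dropped by 2.43 ± 0.17, the zinc finger factor gene Ovol2 fell by 2.44 ± 0.26, the pore-forming macrophage gene Mpeg1 fell by 2.44 ± 0.17 and the long non-coding RNA Dbpht2 fell by 2.45 ± 0.17. Adjusted p values of these 10 genes were at most 4.47e-06.

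**Figure D2:**
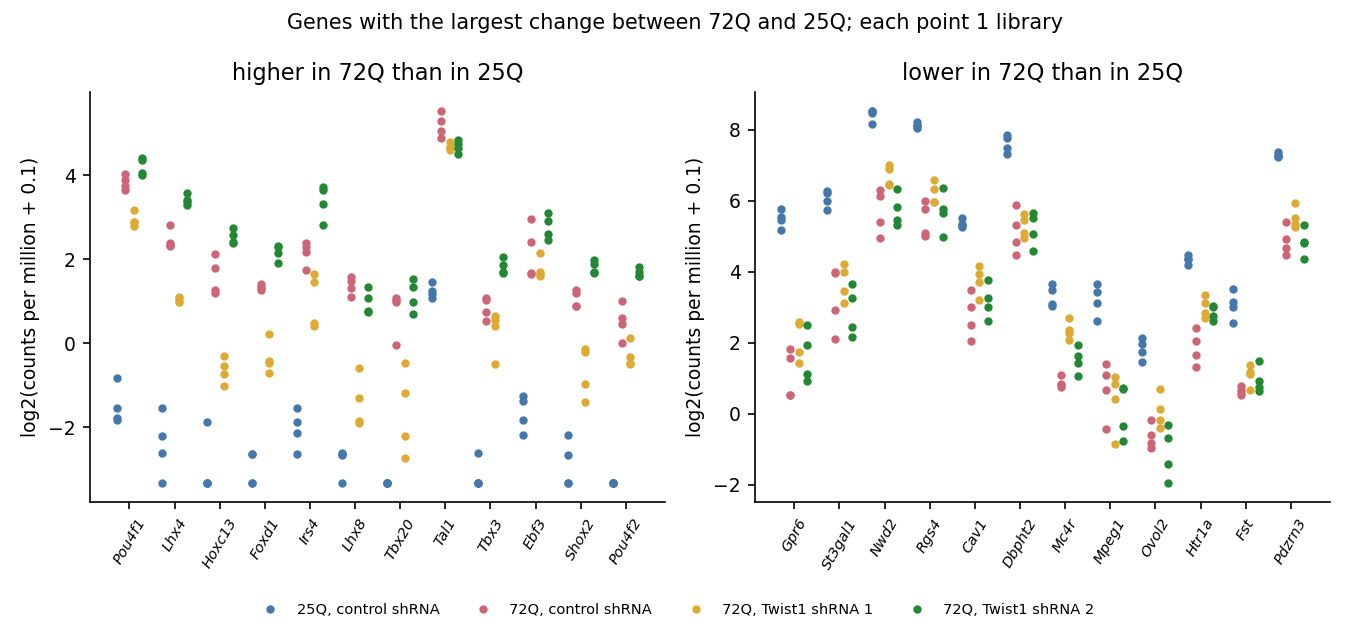
Levels of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in 72Q against 25Q, as log2 of CPM plus 0.1, with 1 point per library and colours for the 4 groups. Pou4f1 averages 0.271 CPM in 25Q and 14.2 CPM in 72Q, and Gpr6 45.4 and 2.25 CPM.

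In the list of HOX and other developmental transcription factors, 33 of 63 members passed the filter on low counts. There, 30 of 33 measured members rose and 0 fell, with the same numbers adjusted over the list alone. Their median log2 fold change was 2.37, the camera adjusted p was 3.54e-11, and an adjusted p = 0.00869 was found with an estimated correlation. Of its members, 9 had 0 counts and 9 had 1 to 3 counts over the 25Q libraries, and with the former at their lower bound the median was 2.90. Members near 0 in 25Q passed the filter through 72Q groups, which favours a rise among them. Of the other 15 members, 12 rose and 0 fell, with a median of 1.69. Their summed 25Q counts ran from 5 (Lhx5 and Tbx5) to 370 (Nkx2-2). Those with few counts there also passed through 72Q groups, so this split carries the same bias. Without the filter, 59 of all 63 members had a higher summed level in 72Q, 0 a lower one and 4 had 0 counts in both. Wt1, a factor of kidney and gonad, rose by 3.06 ± 0.20, Onecut1, a factor of liver and spinal neurons, by 3.09 ± 0.24, and Gata3, a factor of T cells and sympathetic neurons, was at least 22.9-fold higher. HOX genes lie in clusters with antisense transcripts, so single members are uncertain without strand. Summed levels of 1655 olfactory and vomeronasal receptor genes, silent in most tissues, were 7.32 ± 0.94 CPM in 25Q and 9.12 ± 0.861 CPM in 72Q (SD, n = 4), scaled to library totals without TMM factors. In the list of interferon response genes, 20 of 26 measured members rose and 2 fell, with the same numbers adjusted over the list alone. Camera gave an adjusted p of 4.61e-04 at a median of 1.13 log2 units, and an adjusted p = 0.452 with an estimated correlation. Tap1, a peptide transporter of antigen presentation, rose by 1.89 ± 0.11 and Eif2ak2, the double-stranded RNA kinase PKR, by 0.90 ± 0.12, while Stat2, a transcription factor of the pathway, fell by 0.91 ± 0.11. Among p53 targets and apoptosis genes, 19 of 30 measured members rose and 5 fell, with the same numbers adjusted over the list alone. At a median of 0.34 log2 units, the camera adjusted p was 0.00657, and an adjusted p = 0.506 with an estimated correlation. Phlda3, an Akt inhibitor, and Perp, a membrane effector of apoptosis, rose by 1.27 ± 0.090 and 1.19 ± 0.10, and Plk2, a polo-like kinase that is also induced by neuronal activity, fell by 1.16 ± 0.045.

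Neuronal gene groups fell. In the list of cortical projection neuron identity genes, 4 of 35 measured members rose and 29 fell, or 4 and 30 adjusted over the list alone. With a median of -0.78 on the log2 scale, camera returned an adjusted p of 1.18e-20 and an adjusted p = 0.139 with an estimated correlation. Lmo4, a LIM-domain regulator of cortical areas, fell by 1.70 ± 0.054, the transcription factor gene Mef2c fell by 1.63 ± 0.056, from 1800 ± 239 to 585 ± 122 CPM, and the repressor gene Zbtb18 fell by 1.75 ± 0.062. Of voltage-gated channel genes, 5 of 47 measured members rose and 37 fell, or 5 and 39 adjusted over the list alone. The camera test gave an adjusted p of 4.40e-15 (median -0.52 log2 units) and an adjusted p = 0.161 with an estimated correlation. The T-type calcium channel gene Cacna1i fell by 1.81 ± 0.066 and the potassium channel gene Kcnh5 fell by 1.93 ± 0.094. For glutamatergic synapse genes, 3 of 39 measured members rose and 29 fell, or 3 and 30 adjusted over the list alone. The list median was -0.45 log2 units, at a camera adjusted p of 5.39e-12 and an adjusted p = 0.217 with an estimated correlation. The receptor genes Grm7, Gria2 and Grin2a changed by -1.15 ± 0.052, -1.0 ± 0.050 and -1.09 ± 0.080. Among striatal-type neuron genes, 3 of 36 measured members rose and 26 fell, or 3 and 28 adjusted over the list alone. As a set they had a median of -0.68 log2 units and a camera adjusted p of 3.68e-10, and an adjusted p = 0.161 with an estimated correlation. The cannabinoid receptor gene Cnr1 fell by 0.89 ± 0.052, the calcium sensor gene Hpca fell by 0.68 ± 0.052 and the dopamine receptor gene Drd1 fell by 1.73 ± 0.14. Adjusted p values of the genes named for these 4 lists were at most 1.64e-11.

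Genes of inhibitory neurons and GABA receptors moved likewise, in that 3 of 37 measured members rose and 28 fell, with the same numbers adjusted over the list alone. Tested with camera, the list had an adjusted p of 1.46e-06 at a median of -0.52 log2 units, and an adjusted p = 0.349 with an estimated correlation. The GABA-A receptor subunit gene Gabrb2 fell by 0.84 ± 0.048, whereas Lhx8, a factor of cholinergic and GABAergic neurons in the basal forebrain, rose. Of activity-regulated genes, 6 of 39 measured members rose and 24 fell, or 8 and 25 adjusted over the list alone. Their median log2 fold change was -0.48, the camera adjusted p was 8.56e-04, and an adjusted p = 0.428 was found with an estimated correlation. The ERK phosphatase gene Dusp6 and the postsynaptic scaffold gene Homer1 changed by -1.41 ± 0.083 and -0.58 ± 0.046. In the pan-neuronal list, 2 of 25 measured members rose and 17 fell, with the same numbers adjusted over the list alone. Camera gave an adjusted p of 2.60e-05 at a median of -0.35 log2 units, and an adjusted p = 0.349 with an estimated correlation. The vesicle protein gene Syt1 fell by 0.81 ± 0.048 and the neuronal enolase gene Eno2 fell by 0.55 ± 0.045, while Elavl3, a neuronal RNA-binding protein gene, was at -0.054 ± 0.053 (adjusted p = 0.394). Of cholesterol biosynthesis genes, 4 of 25 measured members rose and 19 fell, with the same numbers adjusted over the list alone. At a median of -0.53 log2 units, the camera adjusted p was 3.79e-04, and an adjusted p = 0.56 with an estimated correlation. Insig1, a sterol-dependent regulator of this pathway, fell by 0.50 ± 0.058.

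Markers of other cell types had list medians from -0.069 to 0.21 log2 units. In the astrocyte list, 13 of 22 measured members rose and 0 fell, with the same numbers adjusted over the list alone. With a median of 0.18 on the log2 scale, camera returned an adjusted p of 0.0317 and an adjusted p = 0.56 with an estimated correlation, a call that ended without the experiment block (adjusted p = 0.148). Gja1, the astrocyte gap junction gene, rose by 0.39 ± 0.053. Of neural progenitor and proliferation markers, 13 of 29 measured members rose and 1 fell, with the same numbers adjusted over the list alone. The camera test gave an adjusted p of 0.0345 (median 0.21 log2 units) and an adjusted p = 0.506 with an estimated correlation. The spindle gene Tpx2 and the progenitor factor gene Pax6 rose by 1.22 ± 0.074 and 0.59 ± 0.089, and the matrix gene Tnc fell by 1.31 ± 0.10. Among oligodendrocyte lineage markers, 5 of 16 measured members rose and 2 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.38), and the lineage factor gene Sox10 rose by 0.21 ± 0.060. Of endothelial, mural and meningeal markers, 4 of 12 measured members rose and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.426). Their median was -0.063 and became 0.063 without scaling, and their mean was 0.39, with the growth factor gene Igf2 up by 3.24 ± 0.20 and the pericyte gene Rgs5 at -2.0 ± 0.28. Epithelial-mesenchymal transition genes of the Twist1 literature went both ways, in that 7 of 28 measured members rose and 12 fell, or 9 and 12 adjusted over the list alone (camera adjusted p = 0.0981), and their median of -0.058 became 0.005 with upper-quartile factors and 0.077 without scaling, where 12 rose and 11 fell. Zeb2, Cxcl12 and the fibronectin gene Fn1, all known mesenchymal genes, changed by -0.86 ± 0.050, -2.25 ± 0.17 and -1.54 ± 0.11.

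**Figure D3:**
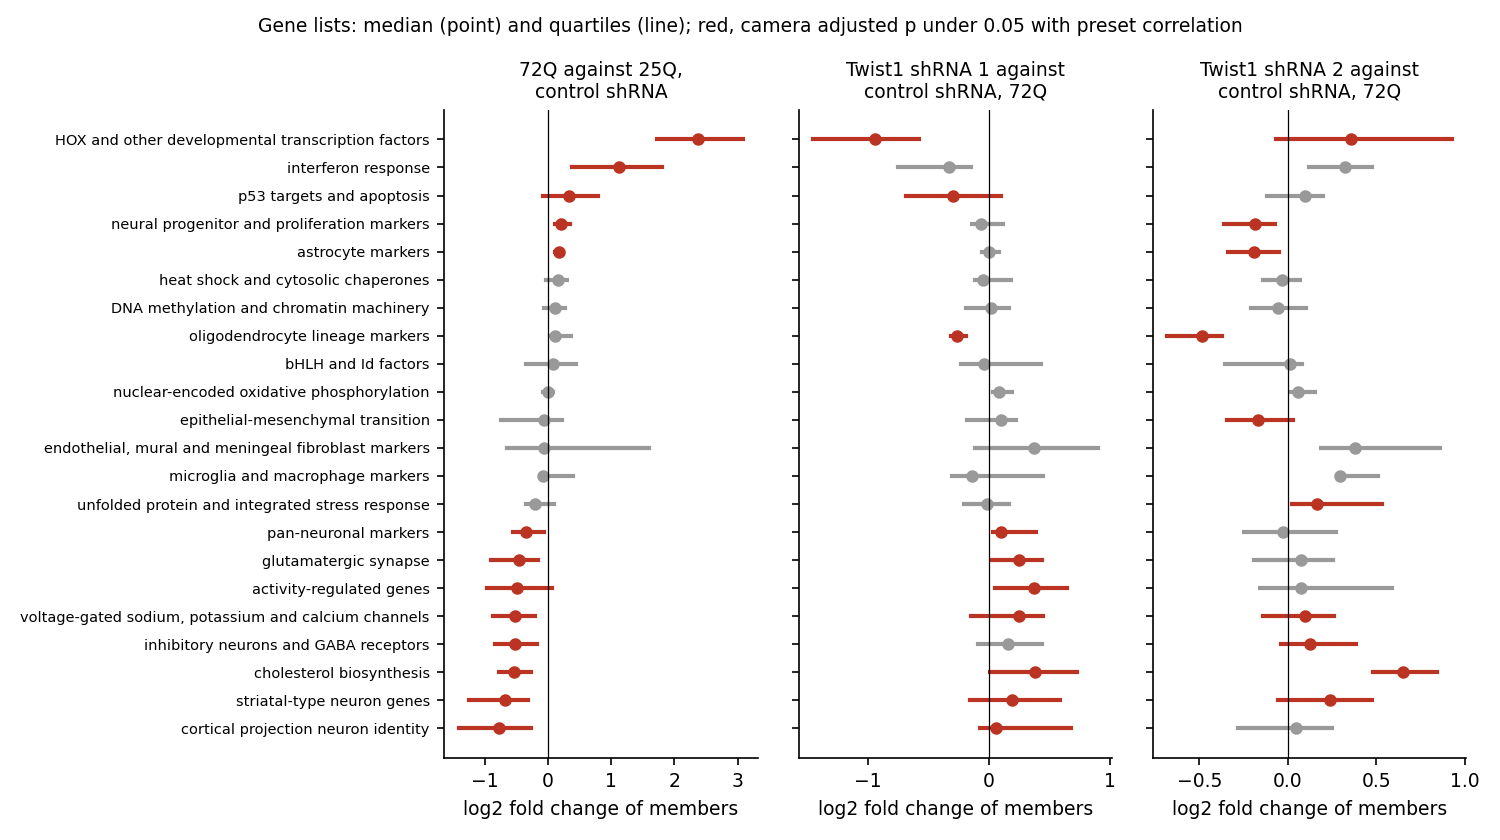
Median (point) and quartiles (line) of the log2 fold changes of members of the 22 gene lists, for 72Q against 25Q, Twist1 shRNA 1 and Twist1 shRNA 2, with lists past a camera adjusted p of 0.05 at the preset correlation in red. The HOX list has medians of 2.37, -0.94 and 0.35, and the cholesterol list -0.53, 0.38 and 0.65, and the directions of these lists were the same under all scalings tried.

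Knockdown of Twist1 in 72Q neurons was compared with the control shRNA to ask what part Twist1 has in transcript levels of these neurons. Both shRNAs raised Grin2a, an NMDA receptor subunit gene, from 11.7 ± 1.81 CPM to 29.4 ± 7.9 and 26.9 ± 3.95 CPM (1.32 ± 0.078 and 1.2 ± 0.078 log2 units), and Sh3bgrl2 from 11.4 ± 1.91 to 23.5 ± 1.89 and 41.7 ± 2.94 CPM. They lowered Tfcp2l1, a pluripotency and kidney factor gene, from 13.1 ± 4.21 to 5.81 ± 1.44 and 5.69 ± 2.14 CPM (-1.14 ± 0.10 and -1.2 ± 0.10), and Hspa12a, an atypical Hsp70 gene, from 113 ± 4.21 to 35.1 ± 2.46 and 59.6 ± 3.81 CPM. Their adjusted p values were at most 8.80e-11. With shRNA 1, 3434 genes rose and 3565 fell, 173 and 258 by at least 2-fold, and without the block 4561 genes were called. With shRNA 2, 3057 rose and 3250 fell, 152 and 65 by at least 2-fold, and without the block the number was 3621. Called genes were higher in 49.1% and 48.5% of cases, against 53.9% and 57.1% with upper-quartile factors and 47.2% and 65.3% without scaling.

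Genes that rose most with both shRNAs, besides Grin2a and Sh3bgrl2, were the pericyte gene Rgs5 (1.94 ± 0.27 and 1.73 ± 0.28), the activin receptor gene Acvr1c (1.52 ± 0.18 and 2.14 ± 0.16), the collagen gene Col1a1 (1.94 ± 0.26 and 1.30 ± 0.28), the glycine receptor gene Glra3 (1.70 ± 0.14 and 1.24 ± 0.15) and the matrix gene Postn (1.55 ± 0.23 and 1.03 ± 0.24). The lipase gene Pnpla3 rose by 1.38 ± 0.15 and 1.19 ± 0.15, the estrogen receptor gene Esr1 by 1.29 ± 0.18 and 1.27 ± 0.18, and the VIP receptor gene Vipr1 by 1.42 ± 0.15 and 1.12 ± 0.15. The strongest decreases beside Twist1, Tfcp2l1 and Hspa12a were in Tedc1, a tubulin-associated complex gene (-1.92 ± 0.13 and -0.99 ± 0.11), Tppp3, a tubulin polymerization gene (-1.94 ± 0.12 and -0.90 ± 0.11), the kinase gene Uhmk1 (-2.41 ± 0.065 and -0.27 ± 0.059), the sodium channel subunit gene Scn3b (-2.37 ± 0.056 and -0.28 ± 0.051), Nudt16l1 (-2.09 ± 0.080 and -0.45 ± 0.068), the actin-binding gene Coro2a (-1.61 ± 0.13 and -0.88 ± 0.12) and Stk40 (-1.45 ± 0.072 and -0.87 ± 0.068). These genes were ranked by the mean of both changes, and adjusted p values in both comparisons were at most 0.00168. Without the block, Postn and Uhmk1 were no longer called with shRNA 2.

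In total 2653 genes were called with both shRNAs in 1 direction, 1329 higher and 1324 lower, and 970 were called in opposite directions. Independent lists would share 695 higher and 767 lower genes, and 1461 in opposite directions. Simulated groups without an shRNA effect gave at most 1 gene in 1 direction, which does not measure what shared controls add where genes do change. The 6 divisions of the controls, with 2 controls per contrast, gave a mean of 1701 genes (1626 to 1913). Without the block the number was 1335. Fold changes of the 2 shRNAs correlated across genes, which are not independent replicates, at r = 0.28, against 0.507 from shared controls alone in the simulations and a mean of 0.173 with divided controls. Their covariance was 0.038 against 0.009 simulated. For the mean of both shRNAs against the control, 6236 genes were called, 2841 higher and 3395 lower, or 3672 without the block. The balance turned with scaling, to 3435 higher and 2898 lower with upper-quartile factors and 3480 and 2824 without scaling.

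Several genes were called with shRNA 1 while the unadjusted p with shRNA 2 exceeded 0.05. With shRNA 1, Ndst4, a heparan sulfate sulfotransferase gene, rose by 1.88 ± 0.14, the matrix gene Thbs1 by 1.72 ± 0.15, the iron exporter gene Slc40a1 by 1.54 ± 0.26, Slitrk6 by 1.52 ± 0.21 and the sodium channel gene Scn7a by 1.48 ± 0.20. Decreases were seen for Lhx8 (-2.65 ± 0.26), Tbx20 (-2.20 ± 0.29), Wdr6 (-1.92 ± 0.052), the kinetochore gene Zwint (-1.86 ± 0.056) and the early B-cell factor gene Ebf1 (-1.81 ± 0.23). With shRNA 2, the orphan receptor gene Gpr101 rose by 1.86 ± 0.14, the exchange factor gene Arhgef16 by 1.66 ± 0.15, Baiap3 by 1.53 ± 0.11 and the transporter gene Slc35d3 by 1.5 ± 0.18. The neuronal RNA-binding protein gene Elavl3 (-1.44 ± 0.054), Mfsd9 (-1.43 ± 0.084), Bean1 (-1.35 ± 0.079) and Zfp362 (-1.22 ± 0.059) fell. All genes of this paragraph also differed between the shRNAs, with an adjusted p of 5.06e-06 or less. Their selection favours such a difference, since each was called with 1 shRNA and had an unadjusted p over 0.05 with the other.

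Cholesterol biosynthesis genes rose with both shRNAs. With shRNA 1, 16 of 25 measured members rose and 2 fell. With shRNA 2, 23 rose and 0 fell. Both pairs were the same adjusted over the list alone. The list median was 0.38 log2 units, at a camera adjusted p of 4.91e-05 and an adjusted p = 0.526 with an estimated correlation for shRNA 1. As a set they had a median of 0.65 log2 units and a camera adjusted p of 8.54e-18, and an adjusted p = 0.219 with an estimated correlation for shRNA 2. Insig1 rose by 0.57 ± 0.058 and 0.93 ± 0.058. Oligodendrocyte lineage markers fell with both, in that with shRNA 1, 0 of 16 measured members rose and 10 fell, or 1 and 10 adjusted over the list alone, and with shRNA 2, 0 of 16 measured members rose and 12 fell, or 0 and 13 adjusted over the list alone. Tested with camera, the list had an adjusted p of 0.0174 at a median of -0.26 log2 units, and an adjusted p = 0.526 with an estimated correlation for shRNA 1, where the adjusted p was 0.124 without the block. Their median log2 fold change was -0.49, the camera adjusted p was 9.62e-07, and an adjusted p = 0.219 was found with an estimated correlation for shRNA 2. Gpr17, a receptor of immature oligodendrocytes, changed by -0.92 ± 0.072 and -0.84 ± 0.072, and Sox10 changed by -0.32 ± 0.060 and -0.64 ± 0.060.

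Several neuronal lists rose with shRNA 1 at the preset correlation. Of glutamatergic synapse genes, 22 of 39 measured members rose and 7 fell, or 24 and 7 adjusted over the list alone. Camera gave an adjusted p of 5.35e-04 at a median of 0.24 log2 units, and an adjusted p = 0.506 with an estimated correlation. The AMPA receptor regulator gene Cacng3 rose by 1.03 ± 0.058 and the scaffold gene Shank3 fell by 0.84 ± 0.051. Of activity-regulated genes, 18 of 39 measured members rose and 3 fell, with the same numbers adjusted over the list alone. At a median of 0.37 log2 units, the camera adjusted p was 0.0106, and an adjusted p = 0.506 with an estimated correlation, with the synaptic immediate early gene Arc up by 0.98 ± 0.091 and Lingo3 at -1.33 ± 0.067. Among striatal-type genes, 12 of 36 measured members rose and 7 fell, or 14 and 7 adjusted over the list alone. With a median of 0.19 on the log2 scale, camera returned an adjusted p of 0.0273 and an adjusted p = 0.56 with an estimated correlation, and Hpca rose by 0.86 ± 0.052. For channel genes, 25 of 47 measured members rose and 12 fell, or 26 and 13 adjusted over the list alone. The camera test gave an adjusted p of 0.0199 (median 0.24 log2 units) and an adjusted p = 0.574 with an estimated correlation, with the calcium channel subunit gene Cacnb4 up by 1.08 ± 0.058. In the projection neuron list, 13 of 35 measured members rose and 6 fell, or 13 and 7 adjusted over the list alone. The list median was 0.059 log2 units, at a camera adjusted p of 0.00642 and an adjusted p = 0.56 with an estimated correlation, and Pcp4, a calmodulin regulator of deep-layer neurons, rose by 1.27 ± 0.086. Pan-neuronal markers showed that 11 of 25 measured members rose and 4 fell, with the same numbers adjusted over the list alone. As a set they had a median of 0.10 log2 units and a camera adjusted p of 0.0115, and an adjusted p = 0.526 with an estimated correlation.

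HOX and p53 genes fell with shRNA 1. Among HOX and other developmental factors, 0 of 33 measured members rose and 20 fell, or 0 and 22 adjusted over the list alone. Tested with camera, the list had an adjusted p of 8.59e-04 at a median of -0.94 log2 units, and an adjusted p = 0.0696 with an estimated correlation. Foxd1 fell by 1.64 ± 0.21 and Gata3 fell by 2.03 ± 0.29. Of p53 targets and apoptosis genes, 4 of 30 measured members rose and 19 fell, with the same numbers adjusted over the list alone. Their median log2 fold change was -0.29, the camera adjusted p was 1.13e-04, and an adjusted p = 0.349 was found with an estimated correlation. Zmat3, a p53-induced zinc finger gene, and the cyclin G gene Ccng1 changed by -1.69 ± 0.048 and -1.05 ± 0.055. Lists that did not pass with shRNA 1 included inhibitory neuron genes (camera adjusted p = 0.0975; 14 of 37 measured members rose and 7 fell), interferon genes (0.166), epithelial-mesenchymal transition genes (0.426), the stress response list (0.621), and markers of astrocytes (0.635), progenitors (0.789) and endothelial, mural and meningeal cells (0.144). Astrocyte genes had a median of -0.004 but a mean of 0.031, and the stress response median changed sign to 0.009 with upper-quartile factors.

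With Twist1 shRNA 2, developmental factor and stress response genes rose, as did 3 neuronal lists. Among HOX and other developmental factors, 14 of 33 measured members rose and 1 fell, with the same numbers adjusted over the list alone. Camera gave an adjusted p of 0.016 at a median of 0.35 log2 units, and an adjusted p = 0.219 with an estimated correlation, and Foxd1 rose by 0.84 ± 0.16. In the unfolded protein and integrated stress response list, 16 of 33 measured members rose and 3 fell, with the same numbers adjusted over the list alone. At a median of 0.16 log2 units, the camera adjusted p was 0.00434, and an adjusted p = 0.506 with an estimated correlation. Atf4, the central factor of the integrated stress response, and its target Ddit3 rose by 0.61 ± 0.070 and 0.57 ± 0.067. Of inhibitory neuron and GABA receptor genes, 13 of 37 measured members rose and 3 fell, with the same numbers adjusted over the list alone. With a median of 0.12 on the log2 scale, camera returned an adjusted p of 0.00375 and an adjusted p = 0.523 with an estimated correlation, with Gabra4 up by 0.81 ± 0.069. For channel genes, 19 of 47 measured members rose and 9 fell, or 20 and 10 adjusted over the list alone. The camera test gave an adjusted p of 0.014 (median 0.10 log2 units) and an adjusted p = 0.56 with an estimated correlation, with the potassium channel gene Kcnc2 up by 1.11 ± 0.071. Striatal-type genes showed that 14 of 36 measured members rose and 2 fell, with the same numbers adjusted over the list alone. The list median was 0.24 log2 units, at a camera adjusted p of 0.0163 and an adjusted p = 0.532 with an estimated correlation. Ppp1r1b, the dopamine signalling phosphoprotein gene, rose by 1.15 ± 0.13 and the striatal-enriched phosphatase gene Ptpn5 fell by 0.85 ± 0.066.

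Astrocyte, progenitor and epithelial-mesenchymal transition lists fell with shRNA 2. Of astrocyte markers, 0 of 22 measured members rose and 13 fell, the same adjusted over the list alone. As a set they had a median of -0.19 log2 units and a camera adjusted p of 0.0014, and an adjusted p = 0.506 with an estimated correlation, and Gja1 fell by 0.59 ± 0.053. Among progenitor and proliferation markers, 1 of 29 measured members rose and 12 fell, the same adjusted over the list alone. Tested with camera, the list had an adjusted p of 0.0248 at a median of -0.18 log2 units, and an adjusted p = 0.506 with an estimated correlation, with the stem cell factor gene Sox2 at -0.40 ± 0.051. Epithelial-mesenchymal transition genes showed that 3 of 28 measured members rose and 11 fell, with the same numbers adjusted over the list alone. Their median log2 fold change was -0.17, the camera adjusted p was 0.0224, and an adjusted p = 0.428 was found with an estimated correlation, and without the block the adjusted p was 0.0777. The metalloprotease gene Mmp14 and the transcription factor gene Zeb1 changed by -0.63 ± 0.065 and -0.48 ± 0.051. The lists of glutamatergic synapse (0.0975), activity-regulated (0.0975), projection neuron (0.618), pan-neuronal (0.38), p53 (0.592) and interferon genes (0.0944) had camera adjusted p values above the threshold. Projection neuron genes had a median of 0.043 and a mean of -0.013, and pan-neuronal genes a median of -0.027, which became 0.011 with upper-quartile factors and 0.048 without scaling. Endothelial, mural and meningeal markers lay higher, with a median of 0.38, at an adjusted p of 0.0975, and of 0.0293 without the block. Within the projection neuron list, Tbr1, a factor of deep cortical layers, fell by 1.19 ± 0.069.

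Whether Twist1 knockdown moved the genes of the 72Q effect back was examined by direction. Calb1, a calcium buffer gene, fell from 55.8 ± 6.31 to 16.3 ± 6.27 CPM in 72Q and rose to 37.3 ± 6.96 and 36.4 ± 8.12 CPM with the shRNAs. Tedc1 rose from 3.38 ± 0.31 to 17.4 ± 4.69 CPM and fell to 4.49 ± 1.04 and 8.67 ± 2.22 CPM. Of the 8628 genes changed by 72Q, 3648 (42.3%) were moved the opposite way with shRNA 1 and 1095 (12.7%) the same way, and with shRNA 2 the numbers were 2378 (27.6%) and 1690 (19.6%). Both shRNAs moved 1372 genes (15.9%) the opposite way, 636 of them higher and 736 lower in 72Q, and 440 the same way. Without the block the 1372 became 597, and with the title number as a block 821. Against 25Q, 522 of the 1372 were still called in the 72Q direction with both shRNAs, 307 in the other direction and 543 not. A median of 10.2% of their log2 change was left. Their selection by opposite movement, against shared controls, favours a small remainder. Over all 8628 genes, 6497 (75.3%) were still called in the same direction and a median of 80.2% was left.

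Genes with the largest change in both directions included, among those higher in 72Q and lower with both shRNAs, Tfcp2l1 (1.79 ± 0.11 in 72Q), Tedc1 (2.30 ± 0.14), the mitotic gene Cdca3 (1.67 ± 0.14), Pld6, a mitochondrial enzyme gene of the piRNA pathway (1.94 ± 0.19), Klhdc7a (1.60 ± 0.23), the lipase inhibitor gene Angptl4 (1.05 ± 0.14), the histone demethylase gene Phf8 (0.63 ± 0.079) and the ciliary factor gene Foxj1 (0.66 ± 0.11). With shRNA 1 and shRNA 2, Cdca3 changed by -0.79 ± 0.12 and -0.94 ± 0.12, Phf8 by -0.77 ± 0.080 and -1.0 ± 0.080, Pld6 by -1.43 ± 0.18 and -0.77 ± 0.16, Foxj1 by -0.97 ± 0.12 and -0.62 ± 0.11, Klhdc7a by -0.90 ± 0.20 and -0.71 ± 0.19 and Angptl4 by -0.65 ± 0.13 and -0.88 ± 0.14. Without the block Angptl4 was called in none of the 3 comparisons and Klhdc7a was not called with shRNA 2, which also held without the 72Q control library of exp108 (-0.45). Among genes lower in 72Q and higher with both were the receptor genes Htr1a, Drd1 and Avpr1a, the last a vasopressin receptor (-2.23 ± 0.15 in 72Q, 1.11 ± 0.17 and 1.07 ± 0.17 with the shRNAs). Others were Rgs5, Postn, Grin2a, Ppp1r1b (-0.97 ± 0.13, 1.17 ± 0.13 and 1.15 ± 0.13), the signalling regulator gene Rgs14 (-1.43 ± 0.14, 0.99 ± 0.14 and 1.31 ± 0.14) and Ankrd33b (-1.01 ± 0.17, 1.25 ± 0.17 and 1.01 ± 0.17). Adjusted p values in the 3 comparisons were at most 0.00389.

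**Figure D4:**
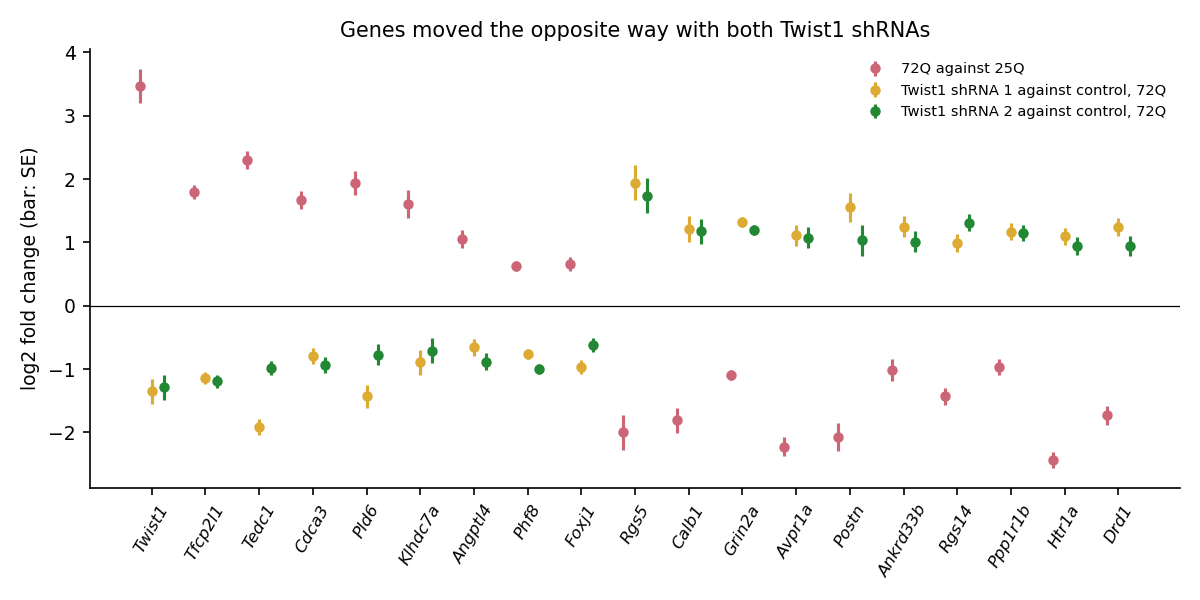
Log2 fold changes with SE of 19 genes with large opposite changes, in 72Q against 25Q and with each Twist1 shRNA against the control in 72Q. Twist1 has 3.47, -1.35 and -1.29, and Rgs5 -2.0, 1.94 and 1.73.

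Because the 72Q controls stand in both contrasts, part of an opposite movement arises without any effect. Simulations without shRNA effects gave at most 2 opposite genes for either shRNA and at most 1 for both. With no effect few genes can be called for an shRNA, so these counts do not measure what shared controls add where genes change. Independent lists would give 2000 opposite genes for shRNA 1, 1803 for shRNA 2 and 758 for both, and for movement the same way 1998 and 1800. With divided controls the opposite means were 2522 and 1510, and 842 (719 to 1174) for both. Means for the same way were 726 and 1162, and 294 for both. These fits had 2 controls per contrast and called a mean of 7142 genes in 72Q, so the numbers for independent lists do not apply to them. Both shRNAs still shared 1 pair of controls there. Fold changes in 72Q correlated with those of shRNA 1 at r = -0.45 across genes (simulated -0.114, divided controls -0.374, from -0.438 to -0.283). For shRNA 2 r was -0.075 (simulated -0.115, divided controls -0.014, from -0.133 to 0.116). Covariances were -0.104 and -0.015, against -0.009 simulated for each.

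The 2 Twist1 shRNAs differed from each other although Twist1 did not differ detectably between them. Arl6ip5, an endoplasmic reticulum protein gene, was at 128 ± 3.34 CPM with shRNA 1 and 28.9 ± 0.96 CPM with shRNA 2 (2.14 ± 0.047 log2 units), and Ssx2ip, a centrosome and adhesion gene, at 18.1 ± 2.85 and 104 ± 8.92 CPM (-2.52 ± 0.063). Hoxd8 and Hoxc13 were lower with shRNA 1, at -3.29 ± 0.24 and -3.13 ± 0.21. Adjusted p values of these genes were at most 1.37e-12. In all, 8030 genes were called, 4116 higher and 3914 lower with shRNA 1, 182 and 404 of them by at least 2-fold, and the share of higher calls was 51.3%, or 48.4% with upper-quartile factors and 36.5% without scaling. Also higher with shRNA 1 were the guanylate cyclase gene Gucy2g (2.67 ± 0.30), the polarity gene Crb1 (2.48 ± 0.13), the proton pump gene Atp12a (2.24 ± 0.19), Pitpnm3 (1.93 ± 0.11) and the ribonuclease gene Rnase4 (1.79 ± 0.20). Tbx20 (-2.56 ± 0.28) and Barx1 (-2.54 ± 0.25), a stomach and tooth homeobox gene, were lower, and adjusted p values of these 7 genes were at most 5.74e-07.

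Gene lists separated the shRNAs as well. Of HOX and other developmental factors, 1 of 33 measured members was higher and 29 lower with shRNA 1, or 1 and 30 adjusted over the list alone. Camera gave an adjusted p of 1.05e-06 at a median of -1.36 log2 units, and an adjusted p = 0.0032 with an estimated correlation. The p53 list had 6 members higher and 17 lower of 30, and the stress response list 7 higher and 19 lower of 33. Both were the same adjusted over the list alone. At a median of -0.43 log2 units, the camera adjusted p was 9.43e-05, and an adjusted p = 0.484 with an estimated correlation for p53 genes. With a median of -0.23 on the log2 scale, camera returned an adjusted p of 0.00715 and an adjusted p = 0.529 with an estimated correlation for the stress response. Interferon genes had 1 member higher and 19 lower of 26, the same adjusted over the list alone, and cholesterol genes 2 members higher and 15 lower of 25, or 3 and 16 adjusted over the list alone. The camera test gave an adjusted p of 0.00795 (median -0.65 log2 units) and an adjusted p = 0.529 with an estimated correlation for interferon genes. The list median was -0.31 log2 units, at a camera adjusted p of 0.00795 and an adjusted p = 0.768 with an estimated correlation for cholesterol genes. Higher with shRNA 1 were astrocyte markers, with 12 members higher and 1 lower of 22, the same adjusted over the list alone, epithelial-mesenchymal transition genes, with 16 members higher and 1 lower of 28, or 18 and 1 adjusted over the list alone, pan-neuronal markers, with 16 members higher and 5 lower of 25, or 17 and 5 adjusted over the list alone, and projection neuron genes, with 19 members higher and 5 lower of 35, the same adjusted over the list alone. Camera adjusted p values were 0.00409, 0.0081, 0.00357 and 0.00409, and the adjusted p was 0.529, 0.484, 0.529 and 0.661 with an estimated correlation. Of the astrocyte genes, the water channel gene Aqp4 differed by 1.04 ± 0.061.

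Words of 7 bases in 3' UTRs were compared with fold changes across genes, which are not independent replicates. With shRNA 1, the word with the lowest z was AAGCTGA (z = -19.2, 2008 of 13598 genes), at z = -1.68 with shRNA 2 and 1.92 in 72Q against 25Q. Its core AGCTGA stood in the 3' UTR of 39.7% of all genes searched and of 147 of 240 genes (61.3%) at least 2-fold lower with shRNA 1. With shRNA 2, the lowest was CAGACCC (z = -12.16, 1635 genes), at z = -0.08 with shRNA 1, and its core AGACCC was found in 29.8% of all genes and 47 of 61 genes (77.0%) at least 2-fold lower. The most extreme word of 72Q against 25Q had a z of 5.56 in size, and the most extreme in simulations without a planted word -4.49. The shRNA 1 word stood in 6 of the 10 named genes lowered most in the mean of both shRNAs, Hspa12a, Uhmk1, Scn3b, Nudt16l1, Coro2a and Stk40. That ranking can favour genes lowered mainly by 1 shRNA. The shRNA 2 word stood in 5 of those 10, Twist1, Tfcp2l1, Hspa12a, Uhmk1 and Coro2a, and in Elavl3, Mfsd9, Bean1 and Zfp362, which shRNA 2 alone lowered. GTATGCA led the genes higher with each shRNA (z = 9.73 and 12.48), and Grin2a, Sh3bgrl2, Acvr1c and Esr1 held it.

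**Figure D5:**
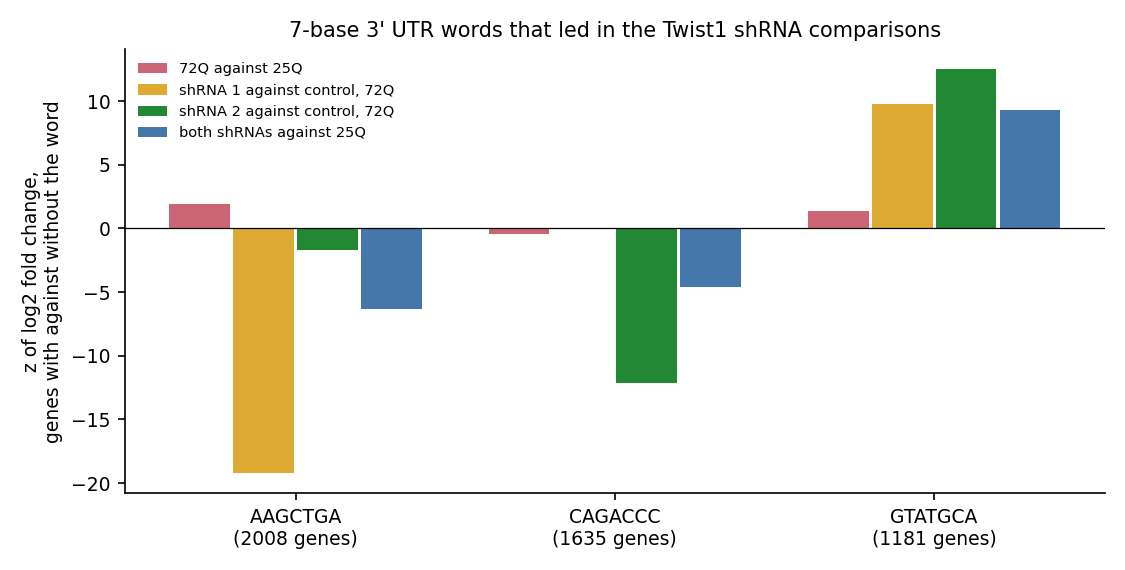
Value of z, across genes, for 3 words of 7 bases in 3' UTRs (AAGCTGA, CAGACCC and GTATGCA) in 72Q against 25Q, each Twist1 shRNA against the control in 72Q, and both shRNAs in 72Q against 25Q, with values below 0 where genes that hold the word were lower. AAGCTGA stands at -19.2 with shRNA 1 and -1.68 with shRNA 2, and CAGACCC at -0.08 and -12.16.

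Finally, 72Q neurons with Twist1 knockdown were set against 25Q neurons with the control shRNA to measure how far they still differed. Pou4f1 stayed at 7.58 ± 0.872 and 18.5 ± 2.66 CPM with the shRNAs (4.95 ± 0.16 log2 units above 25Q for their mean), Tal1 3.44 ± 0.12 and Lmo4 -1.92 ± 0.044. Gpr6 remained -3.57 ± 0.19 and Rgs4 -2.17 ± 0.16 from its 25Q level, with adjusted p values of at most 1.01e-06 for these 5 genes. In this comparison 9432 genes were called, 4593 higher and 4839 lower, 518 and 476 of them by at least 2-fold. Higher calls made up 48.7%, or 61.4% with upper-quartile factors and 70.4% without scaling, which moved the median of all genes from 0.01 to 0.101 and 0.175 log2 units.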

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

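Tests of unequal lowering of Twist1, of silent genes as the whole cause, of cells of another type and of a lower share of neurons were chosen after the results they bear on had been seen.

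The 2 Twist1 shRNAs were set against each other directly, and 8030 genes differed between them, 970 of which had been called in opposite directions against the control. Differences, shRNA 1 minus shRNA 2 in log2 units, were 2.67 for Gucy2g, 2.48 for Crb1, 2.24 for Atp12a, 2.14 for Arl6ip5, 1.93 for Pitpnm3 and 1.79 for Rnase4. They were -3.29 for Hoxd8, -3.13 for Hoxc13, -2.56 for Tbx20, -2.54 for Barx1 and -2.525 for Ssx2ip. Against the control, Atp12a was at 0.41 and -1.82, and Hoxd8 at -1.78 and 1.5. The HOX list had a median of -1.36.

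For this pattern, a difference in Twist1 itself is argued against by its log2 difference of -0.066 between the shRNAs, with a 95% interval of -0.507 to 0.375, and a length bias by a Spearman correlation with gene length of 0.09 across genes. Words in 3' UTRs are consistent with seed-type silencing by each hairpin as 1 source of the difference, with z = -19.2 for shRNA 1 and -12.16 for shRNA 2, each beyond the 5.56 of 72Q against 25Q. Direct silencing through the cores AGCTGA and AGACCC as the whole cause is argued against, since 50% of 6412 genes without either core were called between the shRNAs, 89.5% of the share of 55.8% among all 13598 genes searched. Genes with other low words that lack a core were not taken out, such as GCTGAAT (z = -8.54 with shRNA 1) and GACCCTC (z = -11.61 with shRNA 2). Silencing through such words, or through sites outside 3' UTRs, therefore stays open. Effects further downstream of silenced genes, and a difference in TWIST1 protein, stay open and were not tested.

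The rise of HOX and other developmental factors in 72Q could come from background reads or other cells, or be an effect of 72Q Htt, the difference that the design names. A general rise of silent genes as the whole cause is argued against by olfactory and vomeronasal receptor genes, whose summed level was 0.321 ± 0.226 log2 units higher in 72Q (SD, n = 4 experiments, interval -0.038 to 0.68), far under the HOX list median of 2.373. The receptor sums were scaled to library totals, whereas the HOX median rests on TMM factors. Those factors were 0.898 to 0.949 in 25Q and 0.99 to 1.035 in the 72Q controls, so TMM scaling would lower the receptor difference. On library totals its interval reaches past 0.593, the bound set for a smaller part in the rise, so a smaller part was not decided. Libraries of 25Q had 20188 to 20426 genes with a count against 20544 to 21306 in the 72Q controls. Cells of another type cannot be told apart from a change within neurons by the endothelial, mural and meningeal list, with a median of -0.063, because its 12 measured members of 26 went both ways, Igf2 from 0.395 to 4.75 CPM and Rgs5 from 1.36 to 0.254 CPM. Gene lists of other sources of these factors were not tested.

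The fall of neuronal genes in 72Q was weighed against a lower share of neurons and a length bias. A single common dilution is argued against by the medians of the projection neuron and pan-neuronal lists, which differed by -0.428 log2 units. The difference was -0.411, -0.434, -0.494 and -0.487 in the 4 experiments (-0.457 ± 0.04, SD). A length bias as the cause is argued against for the projection neuron list, whose median was -0.823 after a trend on length was removed and -0.777 before. Other medians moved toward 0, from -0.517 to -0.376 for channels, -0.447 to -0.358 for the glutamatergic synapse and -0.349 to -0.263 for pan-neuronal genes, so length as part of their fall stays open. The share of mitochondrial-genome transcripts was also higher in 72Q controls (3.16 to 3.59%) than in 25Q (2.41 to 2.78%), so a difference in the state of the cultures or their RNA stays open. With shRNA 2 that share was 2.10 to 2.78%. The projection neuron list then had a median of 0.043 against the control, and the other neuronal lists had medians from -0.027 (pan-neuronal) to 0.24 (striatal-type). With shRNA 1 the share was 2.39 to 3.26%, at a projection neuron median of 0.059 and medians from 0.10 (pan-neuronal) to 0.37 (activity-regulated) for the other neuronal lists. Loss of particular kinds of neuron, and lower transcript levels within neurons, stay open too.

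Among 644 groups of 4 values examined, 38 had a library far from the other 3 by Dixon's criterion, where chance gives about 32. Of these values in 25Q, those of Lhx8, Tbx3 and Hoxd8 rested on single counts. In the 25Q group, exp107 gave Hoxc13 at 0.174 CPM against 0 in the others, Cxcl12 at 7.53 against 9.15 to 9.47, and Zeb1 at 129 against 122. The exp109a library gave Lhx8 at 0 against 0.0579 to 0.0635. The exp109b library gave Tbx3 and Hoxd8 at 0.0635 against 0 and Barx1 at 0.508 against 0.183 to 0.232. The 25Q library of exp108 held Sesn2 at 51.2 against 67.5 to 70.8, Dusp6 at 67.1 against 38.5 to 40.3 and Syt1 at 1220 against 1460 to 1470. It also held Kcnh5 at 24.3 against 27.2 to 27.6 and Ndufv1 at 128 against 103 to 106.

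With 72Q and the control shRNA, the library of exp108 held Lhx4 at 6.95 CPM against 4.85 to 5.14 in the others, Tbx20 at 0.875 against 1.87 to 2.01, Fn1 at 8.17 against 17.8 to 18.8 and Sox2 at 60.1 against 75.2 to 76.5. Ppp1r1b was at 5.65 in exp109a against 3.5 to 3.78, Gja1 at 232 in exp107 against 176 to 182, and in exp109b Id2 at 25.8 against 31.1 to 31.5 and Pcp4 at 9.96 against 12.5 to 13.

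With Twist1 shRNA 1, Angptl4 was at 12.3 CPM in exp107 against 1.94 to 3.39 in the others, and Avpr1a at 6.17 against 3.58 to 3.95. The exp109b library held Ebf3 at 4.37 against 2.94 to 3.17, Foxj1 at 6.36 against 4.18 to 4.55, Onecut1 at 3.49 against 1.94 to 2.17 and Id2 at 42.4 against 50.4 to 51.6. Coro2a was at 14.6 in exp108 against 17.6 to 18, Hsp90ab1 at 1940 in exp108 against 1630 to 1680 and Homer1 at 75 in exp109a against 66.4 to 67.7. With Twist1 shRNA 2, exp107 held Zeb2 at 174 against 136 to 139 and Cacng3 at 99.1 against 72.6 to 77.1. It had 20721 genes with a count against 21347 to 21433 in the others and a TMM factor of 1.04 against 1.0725 to 1.078. Other values in this group were Zfp362 at 36.7 in exp109b against 28.8 to 30, Cacnb4 at 64.1 in exp109b against 71.5 to 73, Ankrd33b at 6.62 in exp109a against 3.66 to 4.05, Kcnc2 at 50.3 in exp109a against 37.5 to 38.4, and Fn1 at 8.26 in exp108 against 21.7 to 22.7.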

How the results depend on the processing

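Upper-quartile factors and the absence of scaling were the alternatives chosen after the data had been seen, as was the use of splits within experiments. Without the replicate block, calls numbered 4561 for shRNA 1, 3621 for shRNA 2 and 3672 for their mean against the control, 597 genes were moved the opposite way to the 72Q effect by both shRNAs and 1335 were called in 1 direction with both. Of these calls, 4560, 3621 and 3672 were calls with the block too and 0 lay in the opposite direction. The count for 72Q against 25Q was 6526, within 1.5 times that with the block. With the title number as a block in place of the experiment, 821 genes were moved the opposite way and 1716 were called in 1 direction with both. Among comparisons of named genes, 41 of 407 were no longer called without the block and 28 with the title number, and none turned. Without the block the difference between experiments enters the spread, by construction, and with the title number it enters through 3 of the 4 libraries of 25Q, whose numbers do not match the experiment.

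Divided controls lowered the counts that share them. In 5 of 6 divisions, 874, 751, 787, 719 and 749 genes were moved the opposite way, and 1658, 1645, 1626, 1706 and 1656 were called in 1 direction with both, with 2 controls per contrast in place of 4. Of the gene list tests in the 3 main comparisons, 33 passed at the preset correlation, 1 with an estimated correlation and 31 without the block.

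With each library left out in turn, calls ranged from 7868 to 8429 for 72Q against 25Q, 6187 to 6638 for shRNA 1, 5423 to 5806 for shRNA 2, 5359 to 6088 for their mean, 7209 to 7533 between the shRNAs and 8675 to 9339 for their mean against 25Q. Genes moved the opposite way by both numbered 1026 to 1373 and those called in 1 direction with both 2244 to 2547. Twist1 ranged from 3.14 to 3.75 log2 units in 72Q against 25Q, from -1.50 to -1.22 with shRNA 1 and from -1.39 to -1.19 with shRNA 2. Of 3256 values of named genes in these fits, 3208 kept their direction and their side of the threshold, 28 were no longer called and 20 were newly called.

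Over all alternatives, 7957 of 8128 values of named genes kept direction and side of the threshold, 55 of 407 comparisons had at least 1 change and 0 turned in direction while called. Calls lost and gained among the 407 were 2 and 1 with RLE factors, 2 and 0 with DESeq2, 0 and 5 with limma-voom, 1 and 3 without a filter, 4 and 5 with upper-quartile factors and 9 and 7 without scaling. The cause of these changes was not tested. Depth limits the folds of genes near the floor in 25Q, such as Tbx20 and Hoxd8.

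Other splits of the same libraries were drawn within experiments, which pair the libraries, with the block. For 2 groups of 4 such splits number 8, too few for a share under 0.05. Real counts were 8095 for 72Q against 25Q, 7029 for shRNA 1, 6609 for shRNA 2 and 8057 for shRNA 1 against shRNA 2, and the highest other was 0 for each. For the mean of both shRNAs there were 81 splits. Against 25Q, 1 of 81 called as many genes (5954), and the splits that set apart all shRNA 2 or all shRNA 1 libraries called 4495 and 2320. Splits that mix groups put the differences between groups into the spread, so this rank cannot exclude chance. Against the 72Q control 3 of 81 did (2081, highest other 4911), and the 2 others set apart all shRNA 1 libraries (4911) or all shRNA 2 libraries (3506), so this count does not set the control apart from the shRNAs more than each shRNA from the rest. Splits that mixed groups called 0 genes. These fits use the compared libraries alone and take both shRNAs as 1 group, which puts the difference between them into the spread. Against the 72Q control, separate shRNA groups gave 6483 genes in place of 2081, and the fit to all 16 libraries 6236. Splits that ignore the experiments, drawn without the block, called at most 23 genes where the real ones called 1482 to 5888. For the mean of both shRNAs only 100 of 495 possible splits were drawn in each comparison. Splits that set 1 whole shRNA group apart may therefore be missing among them.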

Other observations

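The slopes across experiments, the test of the word shared by genes higher with both shRNAs and the search of the Twist1 transcript were chosen after the results they bear on had been seen.

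Of heat shock and cytosolic chaperone genes, 13 of 30 measured members rose and 7 fell in 72Q, with the same numbers adjusted over the list alone, and 21 and 5 without scaling (camera adjusted p = 0.223). The cochaperone gene Chordc1 fell by 0.85 ± 0.070, while Hsp90ab1, a constitutive HSP90 gene, rose by 0.59 ± 0.048 with shRNA 1 and 0.39 ± 0.048 with shRNA 2. With shRNA 1 the chaperone list had 8 members higher and 7 lower of 30, or 9 and 8 adjusted over the list alone, and with shRNA 2, 3 members higher and 7 lower of 30, or 3 and 4 adjusted over the list alone (camera adjusted p = 0.621 and 0.898), and its median with shRNA 2 was -0.035, or 0.003 with upper-quartile factors (8 higher and 3 lower) and 0.039 without scaling (9 and 2). With shRNA 1 its median was -0.053 and its mean 0.033. In the unfolded protein and integrated stress response list, 6 of 33 measured members rose and 15 fell in 72Q, with the same numbers adjusted over the list alone, and 11 and 11 without scaling, at a median of -0.075 (camera adjusted p = 0.124). There Atf4 fell by 0.91 ± 0.070, the opposite of its change with shRNA 2, and the autophagy receptor gene Sqstm1 and the stress-induced gene Sesn2 rose by 0.55 ± 0.044 and 0.83 ± 0.074. With shRNA 1, Sesn2 and the chaperone gene Dnajb9 changed by -0.61 ± 0.073 and -0.86 ± 0.069.

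Among nuclear genes of oxidative phosphorylation, 9 of 47 measured members rose and 7 fell in 72Q, or 7 and 7 adjusted over the list alone, 15 and 6 with upper-quartile factors and 29 and 0 without scaling. The camera adjusted p was 0.67, then 0.0501 with shRNA 1 and 0.0572 with shRNA 2. Sdha, a succinate dehydrogenase gene, rose by 0.28 ± 0.045 in 72Q, and Ndufa6, of complex I, rose by 0.41 ± 0.055 with shRNA 1 and 0.27 ± 0.055 with shRNA 2. Of DNA methylation and chromatin genes, 11 of 38 measured members rose and 8 fell in 72Q, with the same numbers adjusted over the list alone, 18 and 6 with upper-quartile factors and 21 and 5 without scaling (camera adjusted p = 0.622), with values of 0.895 and 0.573 for the shRNAs. The histone deacetylase genes Hdac5 and Hdac3 changed by -0.74 ± 0.052 and -0.57 ± 0.050 in 72Q, and the demethylase gene Tet3 changed by -0.62 ± 0.051 and -0.44 ± 0.050 with the shRNAs. For bHLH and Id factors, the family of Twist1, 10 of 22 measured members rose and 6 fell in 72Q, with the same numbers adjusted over the list alone (camera adjusted p = 0.855), with a median of 0.081 and a camera direction of down. With the shRNAs the values were 0.604 and 0.306, at medians of -0.040 and 0.013 and means of -0.004 and -0.031. Tcf4, an E-protein partner of bHLH factors, and Id2, an inhibitor of them, changed by -0.77 ± 0.048 and -1.44 ± 0.083 in 72Q, and Id3 rose by 1.24 ± 0.12 with shRNA 1. Of 5 measured microglia and macrophage markers, 0 rose and 0 fell in 72Q, adjusted over all genes and adjusted over the list alone (camera adjusted p = 0.965), and their median was -0.069, their mean 0.071 and their median without scaling 0.064. Values with the shRNAs were 0.666 and 0.388, and Aif1 rose by 0.51 ± 0.10 with shRNA 2.

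To relate the 72Q effect to that of each shRNA without shared libraries, shRNA fold changes from 1 experiment were regressed on 72Q fold changes from the other 3 across 13599 genes. The slope was -0.278 ± 0.085 for shRNA 1 and -0.038 ± 0.08 for shRNA 2 (SD, n = 4 experiments). Their difference of -0.24 ± 0.038 had the same sign in 4 of 4 experiments, with an exact two-sided sign-flip p of 0.125, the smallest that 4 experiments can give. Genes are not independent replicates of such a slope.

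One hypothesis concerns the control hairpin. The word GTATGCA marked genes higher with both Twist1 shRNAs than in the 72Q control (z = 13.38), and also genes higher with both than in 25Q (z = 9.32), whose libraries carry the same control shRNA but are not the 72Q controls. In 72Q against 25Q, where both sides carry it, z was 1.35. Seed-type silencing by the control shRNA may therefore contribute to the genes higher with both shRNAs. The word stood in 8.7% of all genes searched, in 20.2% of 1288 genes higher with both and in 4.1% of 1283 lower with both. The word was chosen by these same fold changes, so its shares among genes higher or lower with both are no separate evidence. Of 715 genes lower in 72Q and higher with both shRNAs, 15.1% held it, and of 619 genes moved the other way, 3.2%. Of the 10 named genes raised most in the mean of both shRNAs, 4 held it, Grin2a, Sh3bgrl2, Acvr1c and Esr1. Genes higher with both made up 7.6% of genes without the core of this word and 13.9% of genes with it, shares that were not adjusted for the length of 3' UTRs. Without any of the 3 cores, 754 of 5166 genes were still called in 1 direction with both shRNAs, against 2571 of all 13598 searched, and such calls are not explained by these words.

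The leading words of the shRNAs were also sought in Twist1 itself, because a hairpin aimed at it would pair with a site there. In the annotated transcript of 1628 bases (GENCODE M21, GRCm38), AAGCTGA occurred at 1 site, chr12:33958413-33958419 in the coding part of exon 1. CAGACCC occurred at 3 sites, chr12:33958308-33958314 and chr12:33958428-33958434 in the coding part of exon 1 and chr12:33959371-33959377 in the 3' UTR in exon 2, and GTATGCA at 0. Of 6071 genes with a coding transcript of like length, 21.1% held the shRNA 1 word, 19% the shRNA 2 word and 3.51% both. Sequences of the hairpins were not used here.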
